A study of Arabidopsis thaliana with 8 samples.

How the data were processed

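Steady-state transcript levels were measured on 8 Affymetrix ATH1 arrays, each hybridised with RNA from the tip or the base of the Arabidopsis inflorescence stem of the cov mutant or of the wild type Ler-0, with 2 arrays in each of 4 groups. The deposited values are MAS5 signal intensity on a linear scale, per the submitters' processing notes. The version of MAS5 and its detection calls are not given in the sources used here. The table held 22810 probe sets on every array and 0 columns that belong to no sample. The mean signal after trimming 2% of values at each end was 100 on every array, so the arrays were taken as already scaled and no further normalization was applied. The table held 91 values of 0.

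Of the probe sets, 64 were controls and were left out. The annotation used here gave exactly 1 gene for 13513 probe sets, several genes for 503 and no gene for 8730. Symbols were brought up to date through gene identifiers in the RefSeq annotation of the TAIR10.1 assembly for 13436 probe sets, and 77 probe sets with 1 gene had no match there and kept their earlier name. That annotation was used for names and for the order of neighbouring genes alone. Probe sets without a gene stayed in every test and count and are not named. Where a symbol stood for several loci, the locus name was printed instead.

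A pseudocount of 11.85, which is 0.25 of the table median of 47.4, was added before taking log2. The pseudocount draws the differences of genes with low signal toward 0, so the folds given for such genes understate the ratio of the signals. Probe sets whose mean signal over all arrays fell below 21.36, the 30th percentile, were left out as dim. This removed 6823 probe sets and left 15923 for testing, of which 8778 had 1 gene, 301 several and 6844 none.

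Differences were tested with limma 3.58.1 in R 4.3.3. A model of the 4 group means was fitted with lmFit, and eBayes was run with a trend of the variance on the mean signal. The residual degrees of freedom were 4 and the median total after moderation was 10.6. The contrasts were cov minus wild type at the tip, the same at the base, the mean of these differences, the difference between them (base minus tip), and base minus tip within each genotype. P-values were adjusted by the Benjamini-Hochberg method within each contrast, at a threshold of 0.05, and are two-sided. Folds carry 95% confidence limits from the same fit, and errors of log2 differences are standard errors. With 2 arrays per group, the number of arrays limits the precision. The p-values of single probe sets measure only the spread between these samples. That spread may be technical, since the sources used here do not say whether the replicates came from separately grown plants.

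Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, using 1 probe set per gene, that of highest mean signal. At the preset correlation camera takes its degrees of freedom from the number of genes, and at an estimated one from the 4 residual degrees of freedom. List p-values at the preset correlation therefore do not reflect the small number of arrays. The adjustment was made over the lists of one kind within a contrast, with at least 3 tested members required. The model, the contrasts, the filter, the pseudocount, the alternatives, the rule for named genes and 23 gene lists were chosen before the data were examined. Of the 352 entries of these 23 lists, 44 had a named probe set and 39 were tested, which left 8 lists with enough members. A further 14 lists were written after the annotation had been seen and before any test was run, and 30 families of genes that share a symbol stem (6 members or more) were formed from the annotation. Symbols that the annotation gives to other genes (CHI, POR and PS1) were taken out of the added lists after the first run. The lists overlap in part. The wider list of secondary wall loci holds all members of the narrower one on cellulose and xylan. Of the 20 entries of that narrower list 3 were tested, IRX15, IRX15-L and GUT2, and no cellulose synthase gene. Several cold, lignin and cell division genes stand in more than 1 list.

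Named genes are the 10 with the highest and the 10 with the lowest log2 difference past the threshold in each contrast, among probe sets with exactly 1 gene, together with up to 4 members of smallest p in each list that is described. The 4 genes of the COV family were to be named always. Genes outside this rule are said to be so where they appear.

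The fitting procedure was tested on simulated data drawn around the wild type means, with the genotype difference placed at the tip and 50 genes at each fold. At 1.5-fold 0% of the changed genes were recovered, at 2-fold 40%, at 4-fold 88% and at 8-fold 94%. Of 114 calls at the tip 3 (2.6%) were unchanged probe sets. At the base a list of 30 genes had been raised, and 0 of the other probe sets were called there. The list test called the changed list of 30 genes and 0 of 20 unchanged lists. The simulated noise was independent between genes, so the list test was not tried on lists whose genes vary together. Each simulated list held 30 genes, more than several of the lists described here.

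The alternatives tried were a pseudocount of 0 or of the table median, no filter and a filter at the 50th percentile, quantile normalization, median centring, eBayes without the trend, the replicate number as a block, each of the 8 arrays left out in turn, probe sets of several genes left out, a test against a minimum change of 1.5-fold (treat), fits of the compared groups alone, and camera with an estimated correlation. Where an omission leaves a group with 1 array, that array is assumed to vary like those of the other groups. Calls for several probe sets of the same gene were compared for 76 genes. Raw probe intensities were not analysed here.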

Results

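Transcript levels were measured in the inflorescence stems of Arabidopsis thaliana with the ATH1 array, in the cov mutant and in the wild type Ler-0. The cov mutant carries a lesion in COV1, a gene for an integral membrane protein whose loss alters the spacing of vascular tissue in the stem. Tip and base of the stem were sampled separately in each genotype, which gave 4 groups of 2 arrays. Per the labels, plants were at growth stage 6.10 and were grown at 22 °C, 65% humidity and 24 hours of light. The series concerns the role of COV in vascular patterning, and the contrasts address which transcripts differ between the genotypes in each part of the stem, and whether they differ alike in both.

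COV1 and its relatives LCV1, LCV2 and LCV3 had 0 named probe sets in the annotation used here. Their levels are therefore not reported here, and the genotype labels were not checked against the targeted gene. The labels do not give the genetic background of the cov allele or any backcrosses, so differences between cov and Ler-0 are not separated here from differences in background.

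The median signal of the 8 arrays lay between 41.4 and 50.1 and the mean between 127.4 and 135.6. Wild type base array 1 had the lowest median, against 46.4 or more for the other arrays, and the widest spread of log2 signal, with a standard deviation of 1.476 against 1.395 or less. Wild type tip array 1 had the highest difference of 3' from 5' actin probe sets, 0.6936 on the log2 scale against 0.5539 or less, and the lowest mean log2 spike signal, 7.783 against 8.236 or more. Across the 15923 tested probe sets, replicate arrays correlated at r = 0.959 to 0.978, arrays of the same stem part from different genotypes at 0.929 to 0.951, and arrays of different parts at 0.664 to 0.823. These correlations are across probe sets, which are not independent replicates. The first principal component held 76.7% of the variance and separated tip from base. On it both cov pairs lay between the wild type pairs, with scores of -52.41 and -46.56 for cov tips, -68.69 and -68.39 for wild type tips, 52.5 and 44.49 for cov bases and 73.23 and 65.83 for wild type bases. The second component held 8.56% and separated the genotypes.

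At the stem tip, BCAT4, which acts in the methionine chain elongation that leads to glucosinolates, was 10.2-fold higher in cov (95% limits 8.03 to 13.1, n = 2 arrays per group, adjusted p = 3.97e-06). Its mean signal was 560 against 44.4 in wild type. The lipid transfer family gene AT5G55450 was 6.11-fold higher (4.78 to 7.81, adjusted p = 1.64e-05), at 928 against 143. The peroxidase gene AT5G64120 rose by 2.81 ± 0.22 on the log2 scale (adjusted p = 0.000113) and the chitinase genes CHI and AT2G43620 by 2.51 ± 0.26 (adjusted p = 0.00064) and 2.80 ± 0.37 (adjusted p = 0.00275). In the other direction, AT3G28830 was 4.82-fold lower in cov (3.01 to 7.71, adjusted p = 0.00324), at 93.8 against 528. Its neighbours in name AT3G28840 and AT3G28980 were 5.35-fold and 4.07-fold lower. The plot of array signals by group shows BCAT4, AT5G55450, AT5G61720 and AT3G28830 on each array.

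In all, 290 probe sets differed at the tip, 225 higher and 65 lower in cov, and 119 of them had 1 gene. At least 2-fold differences made up 168 of the higher and 56 of the lower calls, and the median standard error was 0.206. For each gene among the 10 most raised or lowered both cov arrays lay outside the range of both wild type arrays, which their choice by size made likely. The other genes among the 10 most raised were AT5G52760 with a log2 difference of 3.21 ± 0.36, and AT3G48640 with 2.85 ± 0.44. They were followed by AT1G65490 with 2.75 ± 0.25, AT1G65500 with 2.57 ± 0.19 and AT3G60420 with 2.50 ± 0.25. Among the 10 most lowered, AT5G61720 had -2.53 ± 0.38, the tetraspanin gene TET15 -2.05 ± 0.32, AT5G07430 -2.04 ± 0.39 and AT5G19580 -2.02 ± 0.29. Below these came AT5G45880 with -2 ± 0.39, the polygalacturonase gene AT3G07820 -1.96 ± 0.41 and AT5G38760 -1.92 ± 0.35. The count fell to 116 without cov tip array 1, 132 without cov tip array 2, 181 without wild type tip array 1 and 176 without wild type tip array 2. Without cov tip array 1 the adjusted p rose to 0.0742 for AT5G61720, 0.0614 for AT5G19580, 0.175 for AT5G07430, 0.224 for AT5G45880, 0.302 for AT3G07820 and 0.201 for AT5G38760. Without cov tip array 2 it rose to 0.0671 for AT3G48640 and 0.0838 for TET15, and without wild type tip array 1 to 0.138 for AT5G07430 and 0.0524 for AT5G45880. Without wild type tip array 2 it was 0.0559 for AT3G48640, 0.0902 for TET15, 0.0705 for AT5G61720, 0.163 for AT5G07430, 0.173 for AT5G45880, 0.217 for AT3G07820 and 0.151 for AT5G38760. Omission of wild type base array 1 or 2 ended the calls of AT3G07820 (0.0858 and 0.0861) and AT5G07430 (0.0529 and 0.0526).

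**Figure D1:**
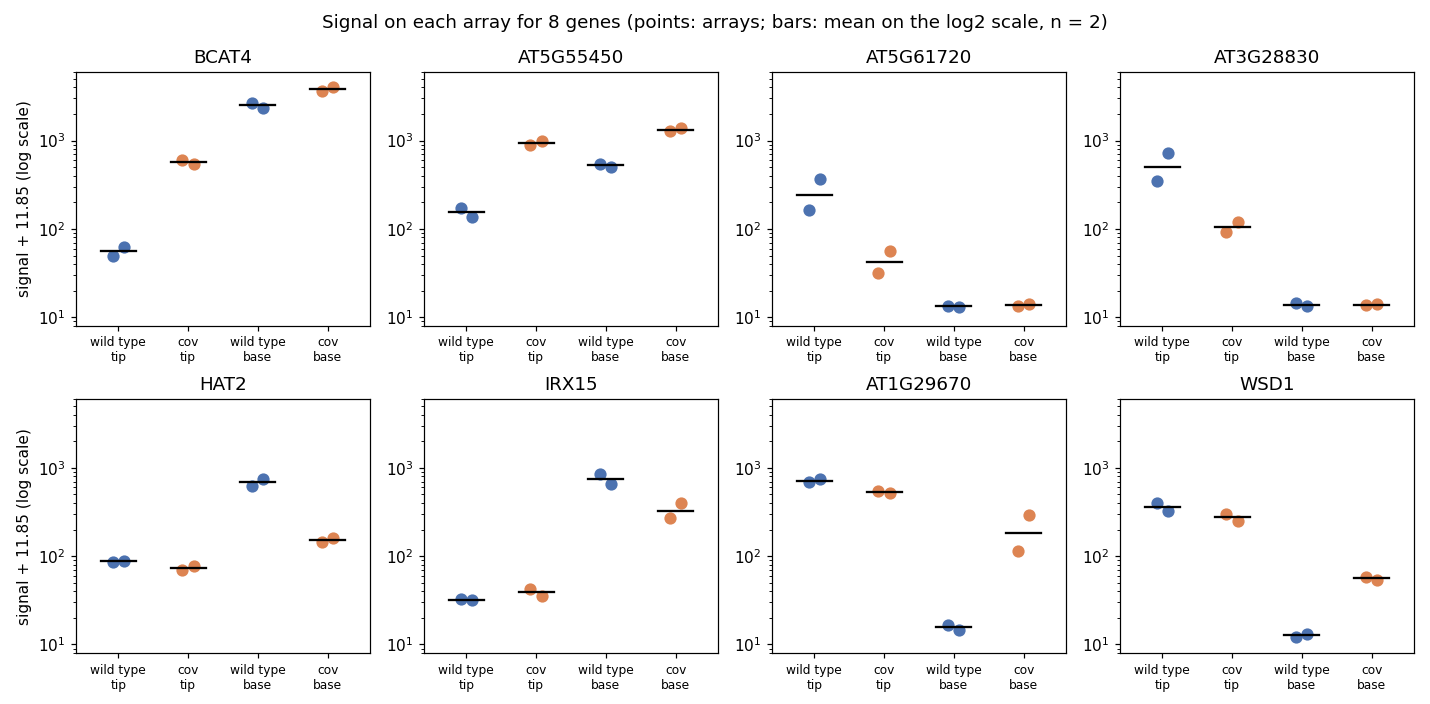
Signal plus the pseudocount of 11.85 on a log axis for 8 genes in the 4 groups of arrays, with 1 point per array and a bar at the mean on the log2 scale (n = 2 arrays per group). In cov tips BCAT4 had a mean signal of 560 and in wild type tips 44.4, while HAT2 had 140 in cov bases and 674 in wild type bases.

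Among gene groups at the tip, the list on myrosin cells and glucosinolates had 3 tested members, of which BCAT4 rose and the other members were not called, the same count as adjusted over the list alone. The list was higher in cov by camera (median log2 difference 0.45, adjusted p = 0.00227), with adjusted p = 0.171 with an estimated correlation and 0.142 without wild type tip array 2. The list on cold, drought and abscisic acid had 3 members and COR15B, a cold-regulated chloroplast protein gene, fell by 1.13 ± 0.17 on the log2 scale (adjusted p = 0.00543). This was 1 of 3 over all genes and 1 of 3 adjusted over the list alone. That list was lower (median -0.34, adjusted p = 0.00788, and adjusted p = 0.34 with an estimated correlation), and its call was lost without wild type tip array 2 (0.252). COR15B itself had an adjusted p of 0.0798 without cov tip array 2 and 0.0524 without wild type tip array 2. The beta-glucosidases, symbol family BGLU with 11 members, were higher (median 0.21, adjusted p = 0.0228, and adjusted p = 0.528 with an estimated correlation, and 0.0627 without wild type tip array 2), with 2 members raised over all genes and 2 adjusted over the list alone. These were BGLU25 at 5.43-fold (4.1 to 7.2, adjusted p = 8.61e-05) and BGLU45 at 3.13-fold (2.37 to 4.13, adjusted p = 0.00104).

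The 33 nuclear photosynthesis and chlorophyll genes and the 69 genes of the chloroplast genome had 0 members called at the tip, over all genes or adjusted over the list alone, at the 1711 probe sets with an unadjusted limma p under 0.05. By camera the nuclear genes were lower (median -0.14, adjusted p = 0.03) and the chloroplast genome higher (median 0.14, adjusted p = 0.03), and both had adjusted p = 0.795 with an estimated correlation. The call for photosynthesis and chlorophyll, nuclear was lost without cov tip array 1 (0.124), wild type tip array 1 (0.113) or wild type tip array 2 (0.0607), and that for the chloroplast genome without cov tip array 1 (0.282) or wild type tip array 1 (0.308). The symbol family BZIP of transcription factor genes (9 members) was also higher (median 0.21, adjusted p = 0.0391, and adjusted p = 0.528 with an estimated correlation), with 0 members called over all genes and 2 raised adjusted over the list alone. That call was lost without cov tip array 1 (0.202), wild type tip array 2 (0.23) or wild type base array 1 (0.0574) or 2 (0.0573), and with the pseudocount at the table median (0.0623).

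Other lists did not pass at the tip. Of 25 genes for wall loosening and xyloglucan, 2 rose over all genes and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.555). They were the xyloglucan transglucosylase genes XTH18, 4.27-fold higher (2.78 to 6.56, adjusted p = 0.00305), and XTH16, 2.14-fold higher (1.54 to 2.96, adjusted p = 0.0271). The call of XTH16 was lost without cov tip array 1 (0.221), cov tip array 2 (0.173) or wild type tip array 2 (0.148). Of 18 secondary wall associated loci 1 rose, both over all genes and adjusted over the list alone, AT1G22480 at 2.38-fold (1.77 to 3.21, adjusted p = 0.00716). Its call was lost without cov tip array 2 (0.0866) or wild type tip array 2 (0.0662), and the list had an adjusted p of 0.494. The 3 secondary wall cellulose and xylan genes had 0 calls (adjusted p = 0.172), as did the 5 procambium, cambium and vascular patterning genes (adjusted p = 0.787).

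The 11 genes of the list on meiosis, anther and pollen had 0 calls at the tip, also adjusted over the list alone (median -0.1, adjusted p = 0.494). Of 15 phenylpropanoid and lignin symbols BGLU45 rose, and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.614). Of 13 seed and dehydration proteins COR15B fell, and 2 fell adjusted over the list alone (list adjusted p = 0.555). The 18 defence and wound symbols had 0 calls over all genes and 2 raised adjusted over the list alone (adjusted p = 0.0981), and the 3 lignin biosynthesis genes 0 calls, and 2 raised and 1 lowered in that way (0.752). The other lists had 0 calls in either way, namely 19 organ and meristem regulators (0.649), 9 auxin related symbols (0.555), 24 genes for mitosis and chromosome segregation (0.693), 36 for vacuolar and secretory trafficking (0.788), 4 for endoplasmic reticulum bodies (0.494), 5 flavonoid genes (0.494), 4 for primary wall and expansion, 3 cell cycle genes and 4 photosynthesis genes of the earlier list (0.787 for each of these 3 lists).

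At the stem base, IRX15, needed for xylan in secondary walls, was 2.27-fold lower in cov (1.64 to 3.14, n = 2 arrays per group, adjusted p = 0.00884), and its relative IRX15-L 1.65-fold lower (1.26 to 2.16, adjusted p = 0.0391). HAT2, an auxin-induced homeobox gene, was 4.49-fold lower (3.51 to 5.76, adjusted p = 0.000105), at 140 against 674. GH3.3, whose product conjugates auxin to amino acids, was 4.54-fold lower (2.32 to 8.89, adjusted p = 0.0154). Raised genes included WSD1, a wax ester synthase, at 4.42-fold (3.33 to 5.86, adjusted p = 0.000158), and the thionin gene THI2.1 at 6.06-fold (3.28 to 11.2, adjusted p = 0.00409). The GDSL lipase gene AT1G29670 was raised 11.5-fold (6.95 to 19.2, adjusted p = 0.000266), with 190 against 3.9. The call of IRX15 was lost without cov base array 1 (0.0561) or wild type base array 1 (0.0885), and that of GH3.3 without wild type base array 1 (0.136) or 2 (0.052). IRX15-L lost its call in 6 of 8 omissions, without cov base array 1 (0.203) or wild type base array 1 (0.218), either cov tip array (0.0723 and 0.0725) or either wild type tip array (0.0511 and 0.0519).

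In all, 881 probe sets differed at the base, 545 higher and 336 lower in cov, and 396 of them had 1 gene. Under median centring 396 were higher and 388 lower. At least 2-fold differences made up 332 of the higher and 159 of the lower calls. Further raised genes were the lectin family gene AT5G03350 with a log2 difference of 3.42 ± 0.25, AT2G10940 with 2.80 ± 0.29, and AT5G63180 with 2.67 ± 0.35. Next were AT4G27652 with 2.57 ± 0.49, AT4G21650 with 2.55 ± 0.28, the GDSL lipase gene AT3G16370 with 2.31 ± 0.27 and DRT100 with 2.28 ± 0.27. Further lowered genes were AT1G64360 with -2.79 ± 0.28, AT3G25930 with -2.30 ± 0.29, AT2G18480 with -2.11 ± 0.26 and the shaggy-like kinase gene AT3G61160 with -2.10 ± 0.20. These were followed by AT1G80170 with -2.01 ± 0.23, AT1G30760 with -2.01 ± 0.39, AT2G20670 with -1.90 ± 0.40 and the CTP synthase gene AT1G30820 with -1.87 ± 0.17. For each named gene among the 10 most raised or lowered both cov arrays lay outside the range of both wild type arrays, as their choice by size again made likely. The count was 440 without wild type base array 1. Without wild type base array 1 or 2 the calls of AT4G27652 (0.0885 and 0.0784) and AT2G20670 (0.154 and 0.0544) were lost, without cov base array 2 those of AT2G20670 (0.0792) and AT1G30760 (0.069), and without wild type base array 2 that of AT1G30760 (0.0965).

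The 3 tested genes of the list on secondary wall cellulose and xylan included no cellulose synthase gene. Of these 3, 2 fell over all genes and 3 fell adjusted over the list alone. The third, GUT2, had a log2 difference of -0.63 (adjusted p = 0.106 over all genes). The list was lower by camera (median -0.72, adjusted p = 0.00131), with adjusted p = 0.213 with an estimated correlation. Of the 18 secondary wall associated loci, which include those genes, 0 rose, 7 fell and 11 were not called, and 9 fell adjusted over the list alone. They included AT2G41610 at 2.66-fold lower (1.97 to 3.58, adjusted p = 0.00214), AT1G22480 at 2.30-fold (1.71 to 3.1, adjusted p = 0.00521) and AT4G27435 at 1.57-fold (1.25 to 1.98, adjusted p = 0.0288). The list was lower (median -0.56, adjusted p = 1.62e-07, and adjusted p = 0.795 with an estimated correlation). The calls of AT1G22480 and AT4G27435 were lost without wild type base array 1 (0.0572 and 0.158). That of AT4G27435 was also lost without cov base array 1 (0.156), wild type base array 2 (0.0541) or either cov tip array (0.0635 and 0.0634). Of the 3 lignin biosynthesis genes, the peroxidase gene PRX52 rose 2.13-fold (adjusted p = 0.0325) and HCT, which acts in monolignol synthesis, fell 1.52-fold (adjusted p = 0.047). Adjusted over the list alone 1 also rose and 1 fell (list adjusted p = 0.688). HCT lost its call in each of the 8 omissions (0.0564 without wild type tip array 1 to 0.199 without cov base array 1). PRX52 lost its call without any array but the wild type tips (0.0527 without cov tip array 1 to 0.137 without cov base array 2).

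**Figure D2:**
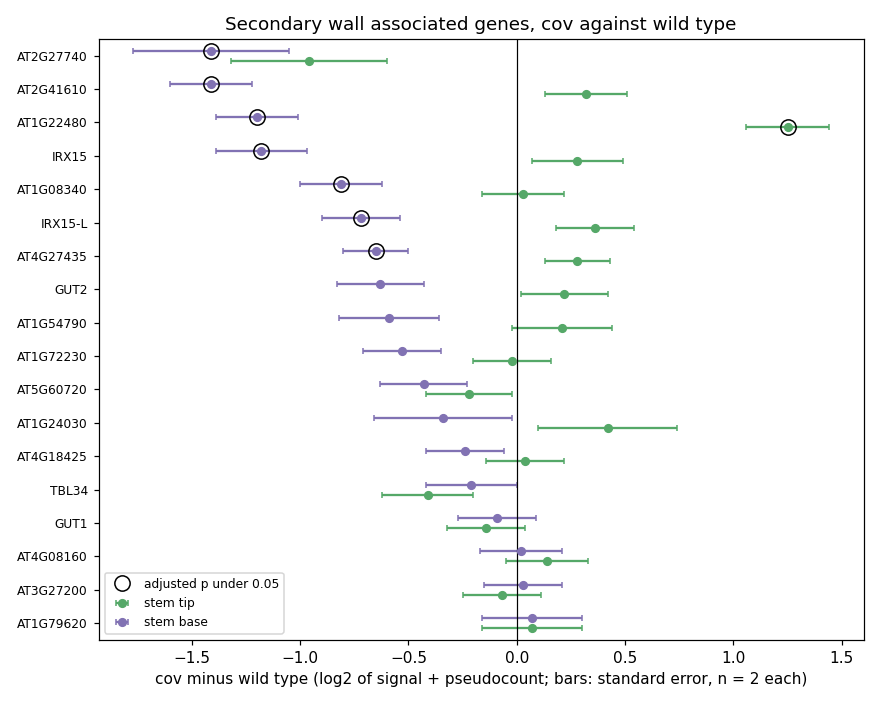
Log2 difference between cov and wild type for the 18 tested secondary wall associated loci at the tip (green) and the base (purple), with standard errors as bars and circles around differences past the test (n = 2 arrays per group). At the base 7 of the 18 fell, and the median was -0.56, against 0.11 at the tip.

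Of 5 tested genes for procambium, cambium and vascular patterning, 2 rose at the base and 3 adjusted over the list alone. LHW, a regulator of vascular initial cells, was 1.90-fold higher (1.43 to 2.53, adjusted p = 0.0152). CLE41, a peptide that maintains the vascular stem cells, was raised 1.63-fold (1.26 to 2.09, adjusted p = 0.0329), and the receptor-like gene MOL1 had a log2 difference of 0.68 (adjusted p = 0.0598). The list of procambium, cambium and vascular patterning genes was higher (median 0.68, adjusted p = 0.0104, and adjusted p = 0.174 with an estimated correlation). Its call was lost without cov base array 2 (0.0567) or wild type base array 2 (0.0717). LHW lost its call without cov base array 1 (0.0507), cov base array 2 (0.0707) or wild type base array 2 (0.0814). CLE41 lost its call without cov base array 2 (0.164), wild type base array 1 (0.154) or 2 (0.0831), or either cov tip array (0.0558 and 0.0563).

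The list on myrosin cells and glucosinolates was again higher at the base (3 members, 2 raised, 2 adjusted over the list alone, median 0.62, adjusted p = 0.0104, and adjusted p = 0.174 with an estimated correlation). UGT74B1, a glucosinolate glucosyltransferase, was 2.38-fold higher (1.65 to 3.41, adjusted p = 0.0116) and BCAT4 1.53-fold (1.2 to 1.96, adjusted p = 0.0497). Without wild type base array 2 the calls of the list on myrosin cells and glucosinolates (0.105), UGT74B1 (0.0921) and BCAT4 (0.189) were lost. Without cov base array 1 those of UGT74B1 (0.0524) and BCAT4 (0.0931) were lost, and BCAT4 also lost its call without cov base array 2 (0.183), wild type base array 1 (0.107) or either cov tip array (0.0944 and 0.0946). Of the 3 genes of the list on cold, drought and abscisic acid, COR15A rose 3.55-fold (2.66 to 4.73, adjusted p = 0.000406) and COR15B 1.97-fold (1.53 to 2.55, adjusted p = 0.0064), with 2 up and 1 down adjusted over the list alone. The list was higher (median 0.98, adjusted p = 0.0283, and adjusted p = 0.291 with an estimated correlation), but not without cov base array 2 (0.0567) or wild type base array 2 (0.105), with the pseudocount at the table median (0.118) or in a fit of the base groups alone (0.0721).

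Of 25 genes for wall loosening and xyloglucan, 3 rose at the base and 4 adjusted over the list alone. They were led by the expansin-like genes EXLA2 at 2.73-fold (1.96 to 3.81, adjusted p = 0.0035) and EXLA1 at 2.49-fold (1.79 to 3.46, adjusted p = 0.00561) and by EXPA15 at 2.75-fold (1.79 to 4.22, adjusted p = 0.0123, and 0.111 without wild type base array 1 and 0.0755 without cov base array 2). The list was higher (median 0.23, adjusted p = 0.0405, and adjusted p = 0.795 with an estimated correlation), but not without cov base array 2 (0.166) or wild type base array 1 (0.625). For wall loosening and xyloglucan the adjusted p was also 0.0753 with the pseudocount at the table median and 0.0583 in a fit of the base groups alone. Of 69 genes of the chloroplast genome, 5 fell and 0 rose, both over all genes and adjusted over the list alone. They included petN, for a subunit of the cytochrome b6f complex, at 2.40-fold (1.87 to 3.07, adjusted p = 0.00135) and psbE, for a subunit of photosystem II, at 1.65-fold (1.34 to 2.04, adjusted p = 0.0121). The call of psbE was lost without cov base array 1 (0.0556), wild type base array 1 (0.0633) or wild type base array 2 (0.0553). The list of the chloroplast genome was lower (median -0.16, adjusted p = 0.012, and adjusted p = 0.795 with an estimated correlation), but not under quantile normalization (0.216) or without cov base array 1 (0.298) or wild type base array 1 (0.625).

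The remaining lists did not pass at the base. Of 9 auxin related symbols 2 fell, HAT2 and GH3.3, both over all genes and adjusted over the list alone (adjusted p = 0.215). Of 18 defence and wound symbols 1 rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.387). The fallen gene was CML41, a calmodulin-like protein gene, at 2.80-fold (1.88 to 4.17, adjusted p = 0.00765, and 0.0684 without wild type base array 2). Among 19 organ and meristem regulators the trihelix factor gene PTL rose 2.55-fold (1.82 to 3.55, adjusted p = 0.00511), and 2 rose and 1 fell adjusted over the list alone (list adjusted p = 0.43). The 13 genes for seed and dehydration proteins had 2 up and 2 down, and 3 up and 3 down adjusted over the list alone (adjusted p = 0.86). The dehydrin gene LTI30 was 2.57-fold lower (1.79 to 3.69, adjusted p = 0.00729, and 0.0698 without wild type base array 1). The 15 phenylpropanoid and lignin symbols had 2 up and 1 down, and 2 up and 2 down adjusted over the list alone (adjusted p = 0.802). Of 4 genes for endoplasmic reticulum bodies JAL23 rose 3.31-fold (2.03 to 5.39, adjusted p = 0.0101, 0.0719 without wild type base array 1 and 0.0601 without cov base array 1), also adjusted over the list alone (list adjusted p = 0.387).

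Of 4 primary wall and expansion genes 1 rose, EXPA15, also adjusted over the list alone (list adjusted p = 0.487). By limma 0 members were called at the base among 24 genes for mitosis and chromosome segregation (adjusted p = 0.215), 3 cell cycle genes (0.445), 4 photosynthesis genes of the earlier list (0.293), 5 flavonoid genes (0.713), 36 genes for vacuolar and secretory trafficking (0.746) and 11 genes for meiosis, anther and pollen (0.511). Adjusted over the list alone these had 0 calls, except for 1 raised member of the list on meiosis, anther and pollen. An unadjusted p under 0.05 was found at the base for 3049 probe sets. Among 33 nuclear photosynthesis and chlorophyll genes 1 rose, and 0 adjusted over the list alone (list adjusted p = 0.387).

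Averaged over both stem parts, AT5G03350 was 5.75-fold higher in cov (4.40 to 7.52, n = 2 arrays in each of 4 groups, adjusted p = 4.93e-05), and BCAT4 3.96-fold (3.34 to 4.71, adjusted p = 1.45e-05). AT5G55450 was raised 3.93-fold (3.3 to 4.67, adjusted p = 1.45e-05) and EXO, a brassinosteroid-responsive gene, 3.13-fold (2.51 to 3.9, adjusted p = 0.000165). On the lower side stood AT4G02340 at 2.58-fold (2.12 to 3.14, adjusted p = 0.000269), HAT2 at 2.31-fold (1.94 to 2.75, adjusted p = 0.000272) and GH3.3 at 2.89-fold (1.80 to 4.65, adjusted p = 0.0191). In all, 737 probe sets differed, 531 higher and 206 lower, and 322 of them had 1 gene. Under median centring 408 were higher and 254 lower. The count was 340 without cov tip array 1 and 373 without cov tip array 2. Other raised genes were AT1G65500 with a log2 difference of 2.09 ± 0.14, CHI with 2 ± 0.18, and AT5G64120 with 1.99 ± 0.16. Behind them came the pseudogene AT3G48650 with 1.94 ± 0.39, AT5G52760 with 1.76 ± 0.25 and AT1G65490 with 1.63 ± 0.17. Other lowered genes were TET15 with -1.5 ± 0.22, AT3G25930 with -1.44 ± 0.21, AT1G64360 with -1.36 ± 0.20, and AT2G18480 with -1.33 ± 0.18. Behind these came AT5G61720 with -1.24 ± 0.27, AT5G45880 with -1.23 ± 0.28 and AT2G27740 with -1.18 ± 0.25. GH3.3 lost its call without cov tip array 1 (0.0746), wild type tip array 1 (0.0799) or wild type base array 1 (0.0949). AT3G48650 lost it without any tip array or wild type base array 2 (0.0579 without cov tip array 1 to 0.0799 without the latter), and AT2G27740 without any array but the cov bases (0.0577 without wild type tip array 2 to 0.0981 without wild type tip array 1). Omissions of cov tip array 1, wild type tip array 2, wild type base array 1 and cov base array 1 ended the calls of AT5G61720 (0.117, 0.0949, 0.0888 and 0.0571) and AT5G45880 (0.115, 0.11, 0.122 and 0.0565). AT5G61720 also lost its call without wild type base array 2 (0.0758), and AT5G45880 without cov base array 2 (0.0631).

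Over both parts, the list on myrosin cells and glucosinolates was higher in cov, with 2 of 3 members raised and 2 adjusted over the list alone (median 0.85, adjusted p = 0.000464, and adjusted p = 0.123 with an estimated correlation). Of 11 beta-glucosidase genes, symbol family BGLU, 4 rose and 5 adjusted over the list alone (median 0.31, adjusted p = 0.0105, and adjusted p = 0.598 with an estimated correlation). The call was lost without cov base array 2 (0.101) or wild type base array 2 (0.0759). BGLU25 was raised 2.38-fold (1.95 to 2.9, adjusted p = 0.000429). Of 5 genes for procambium, cambium and vascular patterning CLE41 rose 1.44-fold (1.21 to 1.72, adjusted p = 0.0292), and 3 rose adjusted over the list alone. That list of procambium, cambium and vascular patterning genes was higher (median 0.34, adjusted p = 0.0331, and adjusted p = 0.218 with an estimated correlation), but not without cov tip array 2 (0.0553), cov base array 2 (0.0904), wild type tip array 2 (0.0847) or wild type base array 2 (0.0656). CLE41 itself lost its call without any array but cov base array 1 and wild type tip array 2 (0.059 without wild type base array 2 to 0.143 without cov tip array 2). Of the 18 secondary wall associated loci AT2G27740 fell, and 2 fell adjusted over the list alone. The list of secondary wall associated loci was lower (median -0.19, adjusted p = 0.00129, and adjusted p = 0.811 with an estimated correlation), but not without cov base array 1 (0.0607) or wild type base array 1 (0.0976). Of 25 wall loosening and xyloglucan genes 5 rose, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.0806). EXLA1 rose 1.93-fold (1.53 to 2.44, adjusted p = 0.00545) and XTH16 1.89-fold (1.5 to 2.38, adjusted p = 0.00584).

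Of the probe sets called higher in cov at the tip, 64 were also called higher at the base, where 7.7 would be shared if the calls were independent, and 9 were lower in both, against 1.37. Opposite calls were 5 higher at the tip and lower at the base, against 4.75, and 6 the other way, against 2.22. Across all 15923 probe sets the genotype differences at tip and base, which share no arrays, correlated at r = 0.13 (Spearman's rho = 0.076, covariance 0.0216), and 51.6% had the same sign. Between single arrays this correlation ranged from 0.048 to 0.16. Probe sets are not independent replicates, so no p is given.

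The genotype difference itself depended on the stem part for 342 probe sets, 176 with a higher and 166 with a lower difference at the base than at the tip, and 155 of them had 1 gene. This balance turned under several alternatives, among them median centring (133 and 156) and the omission of cov tip array 1 (65 and 80), wild type tip array 1 (78 and 86) or wild type tip array 2 (95 and 103). BCAT4 was raised in cov far more at the tip than at the base (interaction log2 -2.74 ± 0.22, adjusted p = 0.000834). HAT2 was 62 in cov tips against 75.6 in wild type tips. At the base it was 4.49-fold lower (interaction -1.92 ± 0.23, adjusted p = 0.0023). WSD1 (2.53 ± 0.26, adjusted p = 0.00164), AT1G29670 (3.96 ± 0.47, adjusted p = 0.0022) and AT4G21650 (3.49 ± 0.39, adjusted p = 0.00175) differed toward higher levels in cov at the base. AT1G22480 (-2.45 ± 0.28, adjusted p = 0.00176) was higher at the tip and lower at the base. Of the 342 probe sets, 241 had differences of opposite sign in the 2 parts, 125 of them higher at the tip and lower at the base and 116 the reverse. The count was 145 without cov tip array 1, 111 without cov tip array 2, 204 without cov base array 2, 164 and 198 without wild type tip arrays 1 and 2, and 142 and 212 without wild type base arrays 1 and 2.

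Further genes with a higher difference at the base were AT5G11420 with 3.13 ± 0.33, THI2.1 with 2.86 ± 0.57, AT2G10940 with 2.85 ± 0.41, and AT3G28840 with 2.81 ± 0.43. Next were AT5G63180 with 2.68 ± 0.50, AT5G59330 with 2.61 ± 0.47 and AT5G61720 with 2.57 ± 0.54. Further genes with a lower difference there were AT3G48640 with -2.95 ± 0.62, AT5G52760 with -2.89 ± 0.51, AT1G80170 with -2.87 ± 0.32, and AT1G64360 with -2.86 ± 0.39. Next came AT3G53980 with -2.75 ± 0.32, CML41 with -2.62 ± 0.37, AT2G43620 with -2.53 ± 0.52 and AT1G10340 with -2.46 ± 0.44. Several of these calls were lost when 1 array was left out. Those of AT5G52760 (0.0515 to 0.0905) were lost without any array but the cov bases, those of AT1G10340 (0.0607 to 0.0934) without any tip array or wild type base array 1, and those of AT5G63180 (0.0567 to 0.0911) without any array but cov base array 1 and wild type base array 2. AT3G48640 lost its call without any array but cov base array 1 and wild type tip array 1 (0.0751 to 0.161), AT2G43620 without any array but cov base array 2 and wild type base array 1 (0.0515 to 0.148), and AT5G61720 without any array but wild type tip array 1 (0.0522 to 0.137). THI2.1 lost it without cov tip array 1 (0.109) or 2 (0.0505), cov base array 1 (0.0569), wild type tip array 2 (0.0898) or wild type base array 1 (0.12), and AT5G59330 without cov tip array 2 (0.0938), cov base array 2 (0.065) or wild type tip array 1 (0.0715) or 2 (0.069).

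Among gene groups, the 3 secondary wall cellulose and xylan genes had lower differences at the base than at the tip, with 1 called over all genes and 3 adjusted over the list alone (median -1.09, adjusted p = 0.000602, and adjusted p = 0.236 with an estimated correlation). IRX15 had an interaction of -1.46 ± 0.30 (adjusted p = 0.0364), a call that was lost without any array but cov base array 2 (0.0574 without wild type base array 2 to 0.138 without wild type base array 1). Of the 18 secondary wall associated loci 3 were called lower and 7 adjusted over the list alone (median -0.63, adjusted p = 4.32e-06, and adjusted p = 0.686 with an estimated correlation). These were AT1G22480, IRX15 and AT2G41610 with -1.73 ± 0.28 (adjusted p = 0.0117, 0.0606 without cov tip array 2 and 0.0539 without wild type base array 1). In the list on cold, drought and abscisic acid, COR15B with 2.11 ± 0.24 (adjusted p = 0.00175) and COR15A with 2.16 ± 0.27 (adjusted p = 0.00285) were called, 2 of 3 members and 2 adjusted over the list alone (median 2.11, adjusted p = 0.00283, and adjusted p = 0.236 with an estimated correlation).

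The 69 genes of the chloroplast genome had lower genotype differences at the base (median -0.35, adjusted p = 6.1e-05, and adjusted p = 0.686 with an estimated correlation), with 2 called over all genes and 2 adjusted over the list alone, psbE with -0.97 ± 0.20 and petN with -1.11 ± 0.23. The call of the chloroplast genome was lost without wild type base array 1 (0.0624). Without cov tip array 2 the adjusted p was 0.188 for psbE and 0.148 for petN, and psbE lost its call without any array but wild type tip array 2 and petN without any 1 of the 8. The 33 nuclear genes for photosynthesis and chlorophyll had higher differences (median 0.16, adjusted p = 0.0169, and adjusted p = 0.686 with an estimated correlation). Of them 0 were called, over all genes or adjusted over the list alone, while 2377 probe sets had an unadjusted limma p under 0.05. The call of photosynthesis and chlorophyll, nuclear was lost without cov base array 2 (0.461) or wild type base array 2 (0.185).

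Along the wild type stem, the secondary wall associated gene AT1G22480 was 70.9-fold higher at the base than at the tip (52.6 to 95.5, n = 2 arrays per group, adjusted p = 1.2e-08) and IRX15 23.1-fold (16.7 to 32.0, adjusted p = 9.98e-08). The tapetum gene AT5G07230 was 52.6-fold higher at the tip (36.8 to 75.1, adjusted p = 4.41e-08) and the anther beta-glucosidase gene ATA27 95.6-fold (72 to 127, adjusted p = 1.02e-08). Their mean signals in wild type tips were 923 and 1340, against 6.1 and 2.3 at the base. With anther genes this high in the tip samples, position along the stem is not separated here from the presence of floral tissue, in either genotype. In all, 7391 probe sets differed, 3510 higher at the base and 3881 lower. The balance turned under median centring, with 4129 higher and 3258 lower and the median difference of all probe sets moved from -0.0139 to 0.107, and with the filter at the 50th percentile (3143 and 3123). Other genes higher at the base were AT1G64360 with a log2 difference of 6.04 ± 0.28, BCAT4 with 5.49 ± 0.16, and AT1G80170 with 5.46 ± 0.23. After them came AT3G23090 with 5.24 ± 0.26, AT3G48640 with 4.99 ± 0.44, AT2G31930 with 4.75 ± 0.30, AT4G28380 with 4.74 ± 0.19 and AT1G10340 with 4.65 ± 0.31. Others higher at the tip were AT1G68875 with -6.79 ± 0.17, AT1G66850 with -6.30 ± 0.21, AT5G62080 with -5.98 ± 0.28, and AT2G20870 with -5.91 ± 0.21. After these came AT1G29670 with -5.50 ± 0.33, AT2G03740 with -5.46 ± 0.17, AT2G03850 with -5.38 ± 0.16 and AT5G22430 with -5.20 ± 0.28.

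Of the 18 secondary wall associated loci 14 were higher at the wild type base and 15 adjusted over the list alone (median 1.68, adjusted p = 9.43e-09, and adjusted p = 0.279 with an estimated correlation). All 3 secondary wall cellulose and xylan genes were higher there, also adjusted over the list alone (median 3.37, adjusted p = 0.000602, and adjusted p = 0.468 with an estimated correlation). Of 24 genes for mitosis and chromosome segregation 17 were lower at the base and 1 higher, the same as adjusted over the list alone (median -1.03, adjusted p = 0.000113, and adjusted p = 0.279 with an estimated correlation). Among them the histone gene HTB1 was 4.77-fold lower (3.43 to 6.62, adjusted p = 1.06e-05) and the Aurora kinase gene AUR1 2.82-fold lower (2.12 to 3.74, adjusted p = 7.41e-05). Of 33 nuclear photosynthesis and chlorophyll genes 17 were lower and 1 higher, the same as adjusted over the list alone (median -0.53, adjusted p = 0.000113, and adjusted p = 0.279 with an estimated correlation). Of 69 chloroplast genome genes 32 were higher and 8 lower, and 34 and 8 adjusted over the list alone (median 0.52, adjusted p = 0.000266, and adjusted p = 0.422 with an estimated correlation). Of 11 genes for meiosis, anther and pollen 7 were lower, and 7 adjusted over the list alone (median -1.73, adjusted p = 0.00341, and adjusted p = 0.32 with an estimated correlation).

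Of 36 genes for vacuolar and secretory trafficking 12 were higher at the wild type base and 3 lower, the same as adjusted over the list alone (median 0.30, adjusted p = 0.0368, and adjusted p = 0.32 with an estimated correlation). The vacuolar processing enzyme gene GAMMA-VPE was 10.4-fold higher (8.05 to 13.4, adjusted p = 1.25e-07). The call of vacuolar and secretory trafficking was lost under quantile normalization (0.0633), in a fit of the wild type groups alone (0.0583) and without wild type tip array 2 (0.168) or wild type base array 1 (0.154). Of 8 autophagy genes, symbol family ATG, 7 were higher, and 7 adjusted over the list alone (median 1, adjusted p = 0.0391, and adjusted p = 0.66 with an estimated correlation). ATG8F was 2.66-fold higher (2.09 to 3.39, adjusted p = 3.47e-05). The call of the family was lost with the filter at the 50th percentile (0.0919), under quantile normalization (0.0642) or median centring (0.0816), in a fit of the wild type groups alone (0.0549) and without wild type tip array 2 (0.0544) or wild type base array 1 (0.0816). All 3 cell cycle genes were lower, also adjusted over the list alone, in a list that did not pass (adjusted p = 0.0506).

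In cov, AT1G22480 was 12.9-fold higher at the base than at the tip (log2 difference 3.69 ± 0.19, n = 2 arrays per group, adjusted p = 5.5e-07), IRX15 8.42-fold (6.08 to 11.7, adjusted p = 3.17e-06) and AT3G45160 19.5-fold (15.3 to 24.8, adjusted p = 5.31e-08). AT5G07230 was 65-fold higher at the tip (45.5 to 92.8, adjusted p = 6.75e-08) and ATA27 86.2-fold (64.9 to 114, adjusted p = 1.45e-08). In all, 4978 probe sets differed, 2455 higher at the base and 2523 lower, a balance that turned under median centring (2708 and 2211) and with the filter at the 50th percentile (2254 and 2148). The count was 2870 without cov tip array 1 and 3263 without cov tip array 2. Other genes higher at the base were AT3G23090 with 3.58 ± 0.26, AT4G28380 with 3.42 ± 0.19, and AT5G18470 with 3.26 ± 0.26. AT1G64360 was 9.02-fold higher (5.91 to 13.8). Then came AT2G31930 with 3.02 ± 0.30, AT1G13470 with 3.01 ± 0.38 and AT1G67865 with 3.00 ± 0.26. Others higher at the tip were AT1G66850 with -6.83 ± 0.21, AT1G68875 with -6.47 ± 0.17, AT5G62080 with -6.28 ± 0.28, and AT2G20870 with -5.57 ± 0.21. Then followed AT3G52130 with -5.44 ± 0.18, AT5G22430 with -5.40 ± 0.28, the GDSL lipase gene AT5G33370 with -5.36 ± 0.43 and AT2G03850 with -5.01 ± 0.16.

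The secondary wall associated loci had 14 of 18 members higher at the cov base, and 14 higher and 1 lower adjusted over the list alone (median 1.44, adjusted p = 1.32e-09, and adjusted p = 0.221 with an estimated correlation). The 3 secondary wall cellulose and xylan genes were higher, also adjusted over the list alone (median 2.51, adjusted p = 0.000145, and adjusted p = 0.21 with an estimated correlation). Of 24 genes for mitosis and chromosome segregation 14 were lower and 1 higher, and 16 and 1 adjusted over the list alone (median -0.75, adjusted p = 3.2e-06, and adjusted p = 0.221 with an estimated correlation). Of 3 cell cycle genes 2 were lower, and 2 adjusted over the list alone (median -0.95, adjusted p = 0.0296, and adjusted p = 0.322 with an estimated correlation). Of 33 nuclear photosynthesis and chlorophyll genes 13 were lower and 1 higher, and 14 and 1 adjusted over the list alone (median -0.44, adjusted p = 0.000755, and adjusted p = 0.237 with an estimated correlation). Of 11 genes for meiosis, anther and pollen 6 were lower, and 6 adjusted over the list alone (median -1.11, adjusted p = 0.000192, and adjusted p = 0.221 with an estimated correlation). Of 36 trafficking genes 8 were higher and 1 lower, and 7 and 1 adjusted over the list alone (median 0.37, adjusted p = 0.0035, and adjusted p = 0.221 with an estimated correlation).

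Of 5 genes for procambium, cambium and vascular patterning 3 were higher at the cov base, and 3 adjusted over the list alone (median 0.57, adjusted p = 0.0429, and adjusted p = 0.21 with an estimated correlation). BRL1, a brassinosteroid receptor of vascular tissue, was 2.52-fold higher (1.78 to 3.57, adjusted p = 0.00122). The call of procambium, cambium and vascular patterning was lost without cov tip array 1 (0.0551), cov tip array 2 (0.0627) or cov base array 2 (0.136), under quantile normalization (0.0636) and with the filter at the 50th percentile (0.2). Of 3 genes for myrosin cells and glucosinolates 2 were higher, and 2 adjusted over the list alone (median 1.91, adjusted p = 0.0296, and adjusted p = 0.21 with an estimated correlation). With the filter at the 50th percentile the adjusted p for myrosin cells and glucosinolates was 0.0711. Of 69 chloroplast genome genes 17 were higher and 10 lower, and 18 and 12 adjusted over the list alone (median 0.26, adjusted p = 0.0455, and adjusted p = 0.612 with an estimated correlation). The call of the chloroplast genome was lost under quantile normalization (0.069) and median centring (0.0586), with the filter at the 50th percentile (0.0845) and without cov tip array 2 (0.146) or cov base array 2 (0.262).

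Further groups that passed at the cov base were the symbol family ATG (6 of 8 higher, adjusted p = 0.0382), the symbol family CYP, which holds cytochrome P450 genes and the cyclophilin gene CYP71 (6 of 12 higher, adjusted p = 0.0405) and the symbol family SWEET of sugar transporter genes (6 of 14 lower, adjusted p = 0.0382). Each had adjusted p = 0.613 with an estimated correlation. They had 7, 6 and 6 such members adjusted over the list alone. Their calls were lost without cov tip array 2 (0.0547 for ATG and 0.0552 for both others), that of ATG also without cov tip array 1 (0.0621) and that of CYP without cov base array 1 (0.077). Under median centring ATG and CYP had 0.0523, and with the filter at the 50th percentile 0.106 and 0.116. For CYP the value was 0.0594 with a pseudocount of 0 and 0.0654 in a fit of the cov groups alone. CYP71B23 was 5.76-fold higher (4.28 to 7.77, adjusted p = 6.38e-06) and SWEET3 5.14-fold lower (3.93 to 6.74, adjusted p = 5.39e-06).

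The gradients of both genotypes were compared across probe sets. Of the probe sets called in each genotype, 2112 were higher at the base in both, where 541 would be shared if independent, and 2264 were lower in both, against 615. Another 2 and 9 were called in opposite directions, against 556 and 598. Of the 4376 called in the same direction, 3527 (80.6%) had a smaller difference in cov, with a median absolute log2 difference of 1.01 in cov and 1.35 in wild type. AT1G22480 and IRX15 stood among them, and so did BCAT4, with 5.49 in wild type and 2.75 in cov. The genotype difference followed the wild type gradient with opposite signs at both ends. Computed from disjoint arrays, its correlation with base minus tip in wild type was r = 0.288 and 0.408 at the tip and -0.312 and -0.341 at the base. With all arrays the values were 0.474 and -0.468. In 50 simulations without a genotype difference, shared wild type arrays alone gave r = 0.112 and -0.113, which are not parts of the observed correlations. The covariance was 0.195 at the tip and -0.231 at the base, against 0.0327 and -0.0327 in the simulations. Of the probe sets called higher in cov at the tip, 187 of 225 were also higher at the base in wild type. Of those called lower in cov at the base, 295 of 336 were, and both counts share the wild type arrays.

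**Figure D3:**
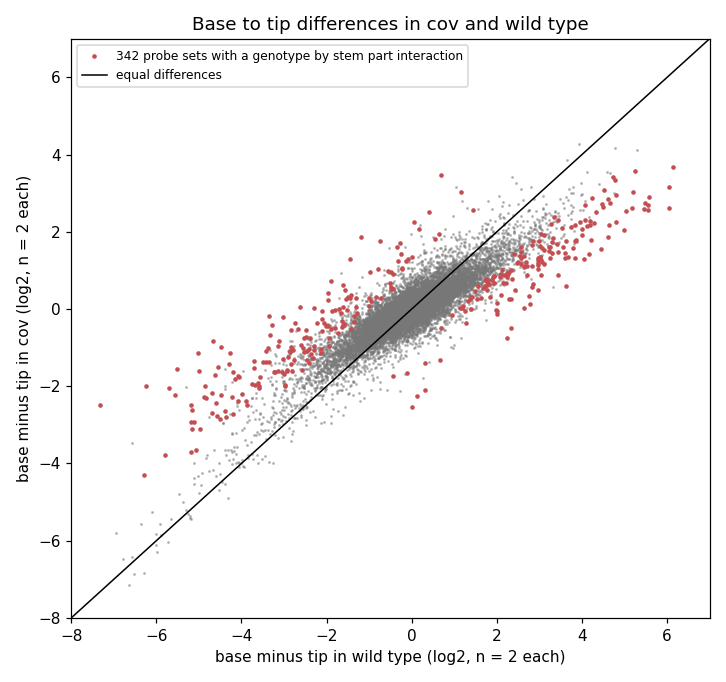
Base minus tip on the log2 scale in wild type (horizontal) and in cov (vertical), with 1 point per tested probe set, a line where both are equal, and the 342 probe sets with an interaction in red. Of the 4376 probe sets called in the same direction in both genotypes, 80.6% had the smaller difference in cov.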

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

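The tests of explanations in this part were chosen after the results they concern had been seen. A test of the difference itself, the interaction of genotype and stem part, singled out 342 probe sets whose genotype difference is not the same at the base as at the tip, and the genes and lists named here passed it. Values are interaction log2 differences, with n = 2 arrays in each of 4 groups, positive where cov minus wild type was higher at the base.

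Lower at the base than at the tip were BCAT4 at -2.74, AT5G52760 at -2.89, AT3G48640 at -2.95, AT5G64120 at -1.64, AT2G43620 at -2.53, AT1G65490 at -2.25, AT5G55450 at -1.28, AT3G60420 at -2.44, AT3G53980 at -2.75 and AT1G10340 at -2.46, all called higher in cov at the tip. Genes called lower in cov at the base and lower in this test were AT1G64360 at -2.86, HAT2 at -1.92, AT3G61160 at -2.13, AT1G80170 at -2.87, AT1G30820 at -1.56, CML41 at -2.62, AT1G22480 at -2.45, IRX15 at -1.46, AT3G23090 at -1.66 and AT4G28380 at -1.33. AT1G22480 was also called higher in cov at the tip.

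Higher at the base than at the tip were AT5G61720 at 2.57, AT3G28840 at 2.81, AT3G28830 at 2.28, AT3G28980 at 1.82 and AT5G19580 at 2.36, all called lower in cov at the tip. Genes called higher in cov at the base were AT1G29670 at 3.96, AT5G03350 at 1.78, AT2G10940 at 2.85, AT5G63180 at 2.68, THI2.1 at 2.86, AT4G21650 at 3.49, AT3G16370 at 2.18, DRT100 at 2.37, WSD1 at 2.53, AT5G59330 at 2.61 and AT5G11420 at 3.13, the last of which was also called lower at the tip. Among the lists, camera gave an adjusted p of 0.000602 for secondary wall cellulose and xylan (lower, median -1.09), 4.32e-06 for secondary wall associated loci (lower, median -0.63), 0.00283 for cold, drought and abscisic acid (higher, median 2.11), 0.0169 for photosynthesis and chlorophyll, nuclear (higher, median 0.16) and 6.1e-05 for the chloroplast genome (lower, median -0.35). With an estimated correlation 0 lists passed, with adjusted p of 0.236 for secondary wall cellulose and xylan and for cold, drought and abscisic acid, and 0.686 for the other 3.

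The first pattern weighed is the smaller difference between tip and base in cov, with a median ratio of 0.759 to wild type over the 4376 probe sets called in the same direction. Noise of shared wild type arrays would leave no correlation of genotype difference and gradient on disjoint arrays. The lowest value at the tip on such arrays was 0.288. Disjoint arrays do not remove error common to both arrays of a wild type group, which is possible if the replicates are technical. Younger segments in cov would make the correlation on disjoint arrays negative at the tip, where the highest was 0.408. Bud-bearing tip tissue in the cov base samples would bring the 50 probe sets most restricted to the tip. Their upper quartile of needed tip signal was 1.31%. For the 357 probe sets called higher in cov at the base and falling toward the base in wild type, the lower quartile was 23.9%. The 50 were chosen by the mean gradient of both genotypes, which favours low cov base levels, and the 357 by high ones. This choice widens the gap, so the comparison alone does not exclude such tissue. The 10 named genes most raised in the wild type tip were ranked by the wild type gradient alone. Of these, AT1G29670 (190 at the cov base, 3.9 at the wild type base) and AT2G20870 (40.2 and 27.6) were higher in cov bases. The rest were at 18.8 or less there and below the wild type base, though at 570 or more in wild type tips. For these genes, the values argue against such tissue at the shares that the 357 needed. A narrower signal scale was argued against by a median ratio of 0.773 after quantile normalization (0.763 to 0.781 by bootstrap over probe sets). That test replaced one on the 50 tip-restricted probe sets after that had given 0.937 (0.875 to 0.964) and left the matter undecided. Probe sets are not independent replicates, and both intervals leave out the spread between arrays. Segments taken closer together along the cov stem predict a positive correlation at the tip and a negative one at the base, as found (-0.341), and cannot be told apart from an effect of genotype at equal positions, because the labels do not record where the segments were taken.

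The second pattern is the lower level in cov tips of genes that were high in the tip. Of the 65 probe sets called lower, 34 were at least 8-fold higher in the wild type tip than in the base. Both choices use the wild type tip arrays, so a high value there by noise favours both. By the mean gradient of both genotypes 17 of the 65 were at least 8-fold higher in the tip, against 171 of all 15923 tested. Whether the 34 are genes of late pollen was not tested. The list on meiosis, anther and pollen did not pass at the tip by camera (adjusted p = 0.494). Fewer flowers in the cov tip samples would lower genes of flowers together. In the list on meiosis, anther and pollen, 7 genes were called higher in the wild type tip (ATA27, AT5G07230, ACT11, SWEET8, EMS1, TET11 and AMS). These had a median of -0.105 in cov tips (-0.323 to 0.0257 by bootstrap over the 7 genes, which leaves out the spread between arrays). Probe sets at least 8-fold higher in the tip on 1 pair of wild type arrays, and at least 2-fold lower in 1 cov tip array, had a median of -1.68 to -0.985 on the other tip arrays over 4 pairings, and the rest of such probe sets -0.282 to 0.0198. These tests replaced one on 171 probe sets chosen by the mean gradient of both genotypes (median -0.21), a choice that a fall in cov tips itself affects. Fewer late floral stages would leave early anther genes in place, and ATA27, AT5G07230, AT1G66850, AT5G62080 and AMS had a median of -0.0985. That explanation cannot be told apart from an effect of genotype on the lowered genes, because the flowers in each sample were not staged on the labels, no list of late floral genes was tested and the early genes had been seen before the test. With the 171 probe sets left out, 17 of the 65 lower calls among them, which was chosen after seeing the data, 272 probe sets differed at the tip, 224 higher and 48 lower.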

How the results depend on the processing

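The omission of probe sets at least 8-fold higher in the tip was chosen after seeing the data, and all other alternatives were set before. The 528 named results (267 genes, list members included) kept their direction under every alternative that gave a value. They were chosen for passing the test with all arrays, and the alternatives reuse these arrays, so a change of direction was unlikely from the start. Their calls were lost for 49 of 528 with a pseudocount of 0, 15 with the table median, 89 without the filter, 26 under quantile normalization, 30 under median centring, 54 without the trend, 19 with the replicate block, 1 without probe sets of several genes, 258 with treat, 44 of 436 in fits of the compared groups alone and 0 of 462 with the filter at the 50th percentile. Leaving out 1 array ended between 67 (wild type tip array 2) and 128 (cov tip array 1) of the 528 calls.

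Leaving out each array in turn gave 116 to 350 probe sets for the tip (290 with all arrays), 440 to 873 for the base (881), 340 to 762 for both parts (737), 111 to 465 for the interaction (342), 6003 to 7434 for the wild type gradient (7391) and 2870 to 5062 for the cov gradient (4978). These fits have fewer arrays, and any other cause was not tested. A test against a minimum change of 1.5-fold is stricter by construction and gave 75, 139, 70, 64, 3173 and 1418 in the same order. The 2 base groups fitted alone, with fewer arrays, gave 490. Without the filter the counts were 484 for both parts and 139 for the interaction, and without the trend the interaction had 227, and the cause was not tested. Without the probe sets at least 8-fold higher in the tip, both parts gave 713 and the interaction 287.

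With camera at an estimated correlation 0 lists were called in each of the 6 contrasts, against 6, 7, 4, 5, 8 and 13 at the preset correlation. The preset correlation is the lower one by construction where genes of a list vary together. The estimated setting also rests on the 4 residual degrees of freedom, and the preset one on the number of genes. How much each of these took from the counts was not tested. Leaving out 1 array gave 1 to 7 lists at the tip and 8 to 14 for the cov gradient. With the filter at the 50th percentile 7 lists were called for both parts and 8 for the cov gradient, where the lists hold fewer members. The correlation of genotype difference and gradient at the base, -0.326 on average over disjoint arrays, was -0.299 with a pseudocount of 0, -0.358 with the table median, -0.28 without the filter and -0.377 with the filter at the 50th percentile, and the cause was not tested. The share of tip calls that were higher in cov was 77.6%, against 87.8% with a pseudocount of 0 and 65.6% with the table median.

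The replicate numbers pair nothing that the sources used here name. With the number as a block the counts were 299, 890, 736, 326, 7366 and 4923. For lists they were 5, 6, 4, 5, 9 and 13, without symbol family BZIP at the tip (0.0525) and wall loosening and xyloglucan at the base (0.051), and with cell cycle in the wild type gradient (0.0478). The correlations of replicate differences between groups ran from -0.0432 to 0.162, the highest between cov tip and wild type tip. They were not set against a null, so a pairing is not excluded. Signals near the level of the pseudocount limit what can be seen of dim genes.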

Other observations

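The tests of COV1 neighbours and of other splits of the arrays were set before their results were seen, and the genes in the next paragraph belong to lists with too few tested members for a list test.

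In wild type, the wax ester synthase gene WSD1 was 28.4-fold lower at the base than at the tip (95% limits 21.4 to 37.6, n = 2 arrays per group, limma adjusted p = 2.97e-08), and in cov 4.91-fold lower (3.70 to 6.51, adjusted p = 8.45e-06). RR16, a cytokinin response regulator gene, was 5.91-fold lower at the base in wild type (3.84 to 9.10, adjusted p = 2.97e-05) and 5.23-fold lower in cov (3.40 to 8.04, adjusted p = 0.000115). The stress-responsive factor genes STZ and WRKY53 were 14.1-fold (5.91 to 33.5, adjusted p = 0.000256) and 9.07-fold (4.15 to 19.8, adjusted p = 0.000437) higher at the base in wild type. In cov they were 3.21-fold (1.35 to 7.63, adjusted p = 0.0437) and 4.19-fold higher (1.92 to 9.16, adjusted p = 0.0103). The call of WRKY53 in cov was lost without cov tip array 1 (0.0708), and that of STZ without any array but cov base array 2 (0.0578 without wild type base array 1 to 0.303 without cov base array 1). The clock gene GI was 1.41-fold lower in cov over both parts (1.17 to 1.69, adjusted p = 0.0443), a call that was lost without any array but cov base array 2 (0.054 without wild type tip array 2 to 0.194 without cov tip array 1).

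The sugar transporter gene SWEET8 was 9.97-fold lower at the wild type base (7.45 to 13.4, adjusted p = 3.39e-07) and 9.40-fold lower at the cov base (7.02 to 12.6, adjusted p = 1.1e-06). The cold-regulated gene COR15A was 24-fold lower at the base in wild type (18 to 32.1, adjusted p = 4.45e-08) and 5.37-fold lower in cov (4.03 to 7.17, adjusted p = 6.79e-06). Among 76 genes with several probe sets, probe sets of the same gene moved in opposite directions with a call for 9 in the wild type gradient and 3 in the cov gradient, and for 0 in the other contrasts.

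A first hypothesis was that calls between the genotypes lie near COV1 because background of another accession is linked to it. Of the 200 tested genes within 100 on either side, 7 (3.5%) were called over both parts, against 310 of 8464 (3.66%) elsewhere (odds ratio 0.954, 95% limits 0.375 to 2.03, one-sided Fisher exact p = 0.602). The upper limit lies below the excess of 3 times that had been set for this explanation. Background differences not linked to COV1 were not tested. The called genes, named because of their position, were AT2G23120 with a log2 difference of 1.11, AT2G19130 with 0.69, AT2G21180 with -0.76, AT2G23200 with 0.68, GH3.3 with -1.53, AT2G18480 with -1.33 and AT2G21850 with 0.74.

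For the contrast over both stem parts, 1 of the 18 splits of the arrays within stem parts, the real one, gave as many as 737 probe sets, and the highest of the other splits gave 342. That split swaps the genotypes in one stem part and so equals the interaction. With 18 splits a share under 0.05 cannot be reached by any count above 0.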
